A study of Homo sapiens with 6 samples.

How the data were processed

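Total RNA from cultured A549 cells, a human lung cancer line, was made into sequencing libraries with an Illumina TruSeq stranded RNA kit, per the labels' protocols. There were 3 wild-type and 3 YTHDF1 knockout libraries, and each sample was put in its group by its title. The authors deposited a table of counts with 1 column of whole numbers per library for 60617 Ensembl genes. Per the submitters' processing notes, the tools named are Trim Galore 0.6.6, STAR 2.7.0d, featureCounts 2.0.1 and edgeR 3.32.1, and the genome build is GRCh38. Which tool did which step, the gene annotation, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Values in the deposited counts show no sign of normalization, since library totals differ, from 27238817 to 40675628.

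Symbols came from a symbol table for 42000 gene identifiers and from GENCODE release 29 for 814 more, while 17811 identifiers had no symbol. GENCODE 29 on GRCh38 also gave coordinates, gene types and exons for 58542 identifiers. It may differ from the annotation the authors counted on. Among genes tested, 66 share a symbol with another gene.

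Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filterByExpr with genotype as the group, which left 18505 genes. Libraries were scaled with TMM factors, and CPM values use these factors. The main test was edgeR's quasi-likelihood test, two-sided, with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 0.062. Standard errors were derived from the fold change and the F statistic. For a group with 0 counts, folds were computed against a floor of 3 counts over the group, and for 1 to 3 counts the ratio is given with an exact 95% counting interval.

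A total of 33 gene lists were written from general knowledge, for pathways, markers of the cell line, markers of other cell types, RNA quality and neighbours of YTHDF1. Each was tested with limma 3.58.1's camera on log2 CPM with a prior count of 2 and a correlation between genes preset at 0.01, with Benjamini-Hochberg adjustment over the 33 lists. Camera compares a list with all other genes tested. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, were run as alternatives.

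The lists, the groups, the tests, the rule for named genes and the alternatives were fixed before the data were examined. The rule named YTHDF1, then the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM, no overlap between the groups and a gene symbol, and then up to 4 members with the smallest adjusted p from each list. Some genes that the rule takes are not reported here. Other genes are said to be chosen after their values were seen. The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library size only, no filter on low counts, a filter of 1 CPM in 3 libraries, a replicate block, leaving out each library, stricter thresholds and the other list tests.

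The tests were tested on simulated counts drawn from the means and library sizes of these libraries, with 200 genes changed. For knockout against wild type, on 18120 genes, edgeR recovered 80.6% of 67 genes changed by 1.5-fold, 92.5% of 67 changed by 2-fold and 100% of 66 changed by 4-fold, and 12 of 194 calls were false. On 18091 genes, camera called the 1 raised list and 0 of 20 unchanged lists at its preset correlation. Genes in that simulation vary independently, so it does not test the preset correlation itself. Both simulations changed far fewer genes than the 9893 of 18505 called in the data. Their rates of recovery and false calls therefore need not hold for these data.

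Libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 4.42 to 6.6 over genes, so all 6 were kept as separate samples. Overlap of exons between genes was computed from GENCODE 29 on each strand, and genes with large overlap are reported as uncertain.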

Results

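RNA was sequenced from A549, a human lung cancer cell line, in wild-type cells and in cells of the same line with a knockout of YTHDF1. YTHDF1 is a cytoplasmic reader protein that binds N6-methyladenosine (m6A) in mRNA. Each group held 3 libraries that the labels call biological replicates. Nothing in the labels says whether these came from separate clones or separate cultures. The p-values below weigh the difference between the groups against the spread among these libraries. Whether that spread includes differences between clones is not known, so the p-values need not hold for other knockout lines. The wild-type libraries held 38225388, 27238817 and 40460782 counts on 60617 genes, and the knockout libraries held 32037107, 40675628 and 40186533 counts. At this depth 3 counts in a library corresponded to between 0.0735 and 0.111 CPM, the count scaled to a fixed library total. Genome coordinates are those of GENCODE release 29 on GRCh38. Means are given ± SD over n = 3 libraries per group, log2 fold changes are knockout minus wild type with the standard error (SE) of the fit, and intervals and floors cover counting error only.

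YTHDF1 RNA was lower in the knockout libraries and was still detected in each of them. The gene lies on chromosome 20 from 63195429 to 63216234 on the minus strand. Its level was 98.0, 104 and 96.4 CPM in the wild-type libraries and 48.6, 48.6 and 47.1 CPM in the knockout libraries. YTHDF1 fell by 1.05 on the log2 scale (SE 0.0526) from 99.4 ± 3.89 to 48.1 ± 0.87 CPM, with an adjusted p of 7.84e-18 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The part of the gene that was edited is not given in the sources used here, and a gene-level count does not measure protein.

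**Figure D1:**
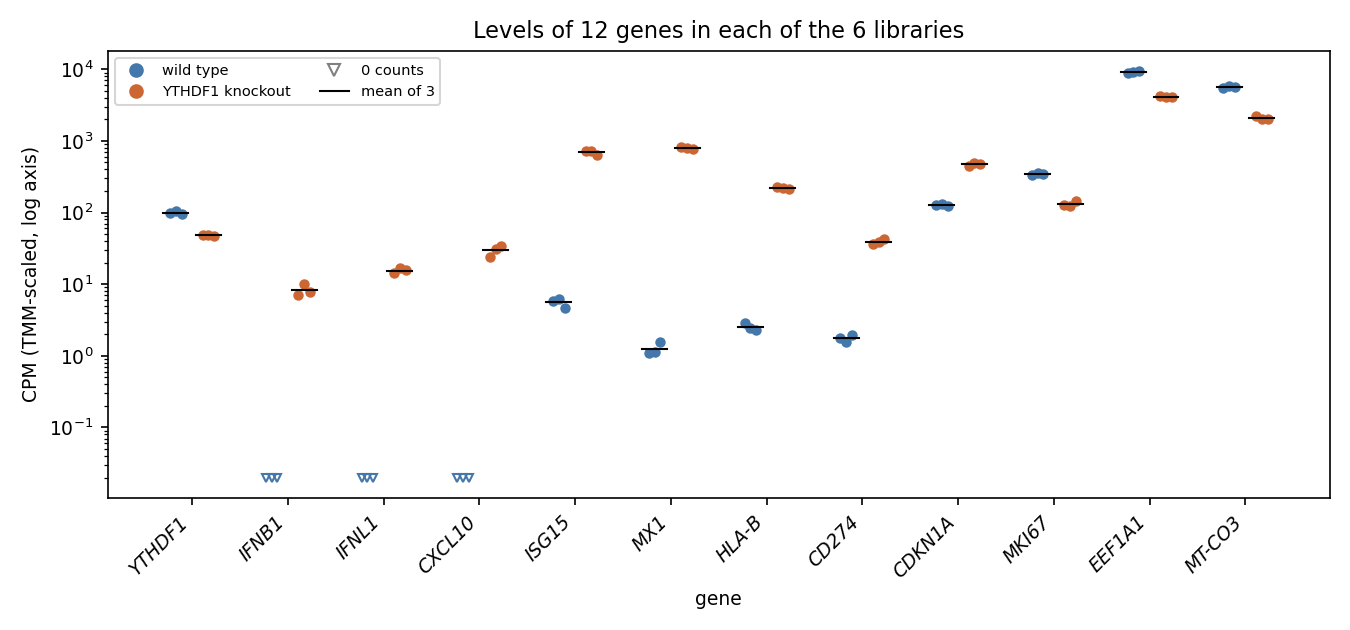
CPM of 12 genes on a log axis in each of the 3 wild-type and 3 knockout libraries, with points for libraries, black lines for group means and open triangles for libraries with 0 counts. YTHDF1 fell from a mean of 99.4 to 48.1 CPM, while IFNB1, IFNL1 and CXCL10 had 0 counts in every wild-type library and counts in every knockout library.

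The series compares the transcriptomes of wild-type and YTHDF1 knockout cells, under a title that links YTHDF1 to R-loops and to innate immunity. The genes with the largest rises were interferons and genes known to be induced by interferon. GBP4, an interferon-induced guanylate-binding protein, had 0 counts in the wild-type libraries and 132 ± 14.6 CPM in the knockout libraries, which was at least 4640-fold higher when the wild-type group is set at a floor of 3 counts over the group. By the same floor the chemokine CXCL11 was at least 1310-fold higher, the tryptophan-degrading enzyme IDO1 at least 1230-fold higher, the chemokine CXCL10 at least 1060-fold higher and the transcription factor ETV7 at least 389-fold higher. The type III interferons IFNL1, IFNL3 and IFNL2 were at least 545-fold, 521-fold and 509-fold higher, with 15.5 ± 1.2, 14.9 ± 2.29 and 14.5 ± 1.21 CPM in the knockout libraries. IFNL2 and IFNL3 are near-identical copies, so the division of reads between them is uncertain.

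IFITM1, an interferon-induced membrane protein, had 3 counts in the wild-type group and 112 ± 6.43 CPM in the knockout libraries, a ratio of 3900 with an exact 95% counting interval of 1330 to 18900. XAF1, an interferon-induced regulator of apoptosis, rose by 11.76 on the log2 scale (SE 0.153) from 4 counts in the wild-type group to 144 ± 3.92 CPM. In GENCODE 29, 32.5% of the exonic bases of IFITM1 overlap another gene on the same strand and 38.3% of those of XAF1 overlap a gene on the opposite strand, so both levels are uncertain. IFNB1, the type I interferon beta, was chosen after its values were seen; it had 0 counts in the wild-type libraries and 8.22 CPM in the knockout libraries, at least 291-fold higher.

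Among genes with a mean of at least 5 CPM, the largest fall was that of the neuropeptide precursor gene VGF, which fell by 3.73 on the log2 scale (SE 0.126) from 27.4 ± 3.53 to 2.07 ± 0.239 CPM. The sulfate transporter gene SLC26A2 fell by 3.06 (SE 0.0554) from 730 ± 30.6 to 87.3 ± 9.3 CPM, the most abundant of the 10 largest falls. The neuropeptide receptor gene NPBWR1 fell by 2.63, KLHL4 fell by 2.58, the matrix glycoprotein gene TNC fell by 2.41, the bicarbonate transporter gene SLC4A8 fell by 2.39, the metalloproteinase inhibitor gene TIMP4 fell by 2.38 and the sorting receptor gene SORL1 fell by 2.23. PRR11 fell by 2.51 from 74.7 ± 0.992 to 13.1 ± 0.46 CPM, and PRR11-AS1, which lies on the opposite strand within the span of PRR11, fell by 2.60. In GENCODE 29, 30.2% of the exonic bases of PRR11-AS1 and 2.4% of those of PRR11 overlap a gene on the opposite strand, and whether counting used strand is not given in the sources used here, so the level of PRR11-AS1 is uncertain.

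Of 18505 genes tested, 9893 (53.5%) changed at an adjusted p threshold of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5028 higher and 4865 lower in the knockout libraries. The larger changes were mostly rises: 1472 genes rose and 822 fell by at least 1 on the log2 scale, and 268 rose and 28 fell by at least 3. The knockout and wild-type libraries did not overlap for 58.9% of the genes, where chance gives 10% for 3 against 3. With a fold change of at least 1.5 built into the test, the count was 2585. A sign of RNA quality differed between the same groups. Mitochondrially encoded mRNAs took between 5.76% and 5.92% of the counts in the wild-type libraries and between 3.72% and 3.98% in the knockout libraries. This difference stands beside each gene group described here. The other lists fixed as signs of RNA quality did not pass camera in the main setting. The adjusted p was 0.108 for replication-dependent histone genes, or 0.0284 with the filter of 1 CPM in 3 libraries and 0.467 with an estimated correlation. For nuclear long noncoding RNAs and small RNA hosts it was 0.944.

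All 47 interferon-stimulated genes of the list rose, and all 47 also rose when adjusted over the list alone. The median log2 fold change was 5.69, and it was 5.69 with genes at 0 counts set to the floor. IFIT2, an interferon-induced RNA-binding protein, rose by 9.35 (SE 0.0649) from 3.15 ± 0.233 to 2082 ± 96.2 CPM. IFIT1 rose by 8.17, IFI6 by 7.38 and IFIT3 by 7.29, the last from 10.5 ± 0.92 to 1650 ± 36.9 CPM. The share of counts on these 47 genes was between 0.1% and 0.101% in the wild-type libraries and between 2.28% and 2.34% in the knockout libraries. Camera gave the list an adjusted p of 1.65e-33 with Benjamini-Hochberg adjustment over 33 lists, and an adjusted p = 0.0119 with an estimated correlation. Of the 17 lists past the threshold of camera, 11 higher and 6 lower, no other list kept its call with an estimated correlation.

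Of 29 genes listed for the sensing of foreign or misplaced nucleic acid, 24 were tested. Among these, 21 rose and 1 fell, with the same counts, 21 and 1, adjusted over the list alone. IFIH1, a sensor of long double-stranded RNA, rose by 6.84 from 4.39 ± 0.729 to 511 ± 17.7 CPM, and RIGI, a sensor of RNA with a triphosphate end, rose by 5.37 from 15.6 ± 2.16 to 650 ± 34.8 CPM. IFI16, a DNA sensor, rose by 3.62 and SAMHD1, a nucleotide triphosphohydrolase, rose by 4.16. MAVS, the mitochondrial adaptor of RIGI and IFIH1, was the gene that fell and was chosen after its values were seen; it fell by 0.24. The camera test of the list gave an adjusted p of 1.67e-09, and an adjusted p = 0.0574 with an estimated correlation.

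Among interferons, cytokines and chemokines, 27 of 32 listed genes were tested. Of these, 21 rose and 3 fell, and the counts were 21 and 3 adjusted over the list alone. The median log2 fold change was 1.41, also with genes at 0 counts set to the floor. The death ligand gene TNFSF10 rose by 7.14 from 0.527 ± 0.519 to 65.2 ± 3.2 CPM, and the chemokine gene CXCL16 rose by 2.60 from 8.62 ± 0.975 to 52.5 ± 1.55 CPM. The 3 genes that fell, chosen after their values were seen, were IL11 (fell by 1.84), IFNE (fell by 0.37) and CXCL2 (fell by 0.28). Camera gave an adjusted p of 1.4e-07, and an adjusted p = 0.0574 with an estimated correlation.

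Genes for antigen presentation to T cells were tested for 24 of 29 listed members. Of these, 19 rose, or 20 when adjusted over the list alone, and 4 fell by either adjustment. HLA-B, a class I heavy chain, rose by 6.46 (SE 0.075) from 2.51 ± 0.301 to 221 ± 8.63 CPM, the peptide transporter gene TAP1 rose by 4.57 from 17.4 ± 1.78 to 411 ± 13.5 CPM, the class I light chain gene B2M rose by 3.21 from 186 ± 5.56 to 1721 ± 56.6 CPM, and NLRC5, a transactivator of class I genes, rose by 4.04. The class I heavy chain genes are close paralogs, so the division of reads among them is uncertain. The genes that fell, chosen after their values were seen, were the chaperone genes CALR (fell by 0.68), CANX (fell by 0.37) and PDIA3 (fell by 0.28), and HLA-DMA (fell by 0.93). Camera gave an adjusted p of 4.84e-09, and an adjusted p = 0.0574 with an estimated correlation.

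Immune checkpoint ligands and regulators were tested for 27 of 32 listed genes. Of these, 16 rose and 2 fell, or 17 and 2 adjusted over the list alone. CD274, which encodes PD-L1, rose by 4.47 (SE 0.114) from 1.76 ± 0.195 to 39.4 ± 3.51 CPM. CEACAM1 rose by 4.53 from 6.55 ± 1.08 to 151 ± 6.83 CPM and NECTIN2 rose by 1.33 from 123 ± 0.902 to 310 ± 7.91 CPM. The list also holds IDO1. FGL1 (fell by 0.53) and ENTPD1 (fell by 0.30), chosen after their values were seen, were the genes that fell. In camera the list had an adjusted p of 6.54e-06, and an adjusted p = 0.0574 with an estimated correlation.

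Most NF-kB target genes and most p53 target genes rose. Of 25 NF-kB targets, 22 rose and 1, PLAU, fell by 0.47, and the counts were 22 and 1 adjusted over the list alone. The superoxide dismutase gene SOD2 rose by 2.02 from 300.3 ± 27 to 1215 ± 17.5 CPM, the deubiquitinase gene TNFAIP3 by 2.15, the apoptosis inhibitor gene BIRC3 by 2.18 and the complement gene C3 by 1.34. Of 29 p53 targets, 24 rose and 3 fell, and the counts were 24 and 3 adjusted over the list alone. The cell cycle inhibitor gene CDKN1A rose by 1.91 (SE 0.046) from 126 ± 4.6 to 472 ± 24.8 CPM, the secreted factor gene GDF15 by 2.03, the p53 ubiquitin ligase gene MDM2 by 1.29 and the death receptor gene TNFRSF10B by 1.25. ZMAT3 (fell by 0.66), CCNG1 (fell by 0.35) and CYFIP2 (fell by 0.24), and PLAU above, were chosen after their values were seen. Camera gave the NF-kB list an adjusted p of 4.5e-09 and an adjusted p = 0.149 with an estimated correlation, and it gave the p53 list an adjusted p of 4.38e-07 and an adjusted p = 0.276 with an estimated correlation.

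**Figure D2:**
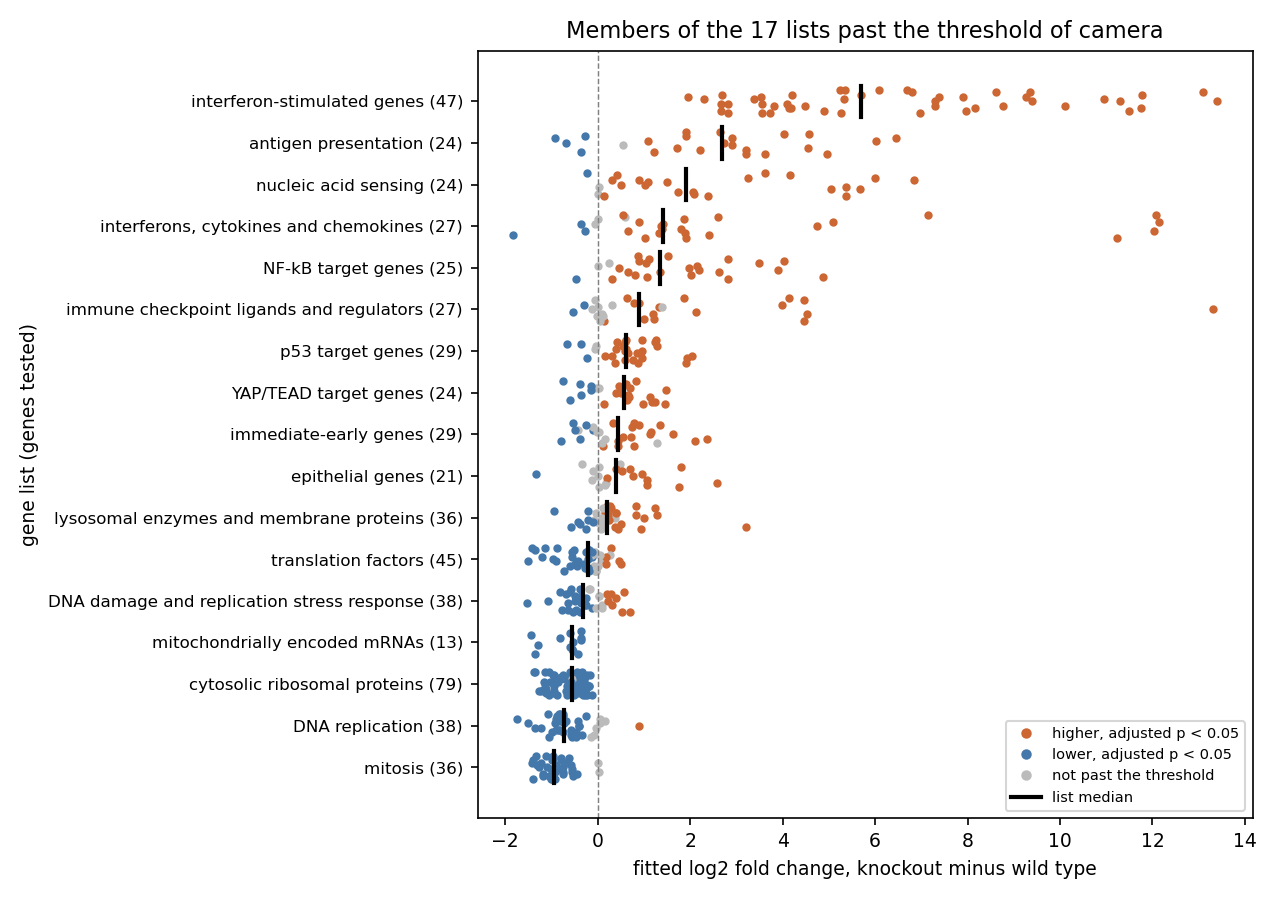
Fitted log2 fold change (knockout minus wild type, x axis) of each tested gene in the 17 lists past the threshold of camera, with points for genes coloured by edgeR's call and black bars for list medians. The medians run from -0.94 for mitosis to 5.69 for interferon-stimulated genes, and fitted values of genes with 0 counts in a group depend on the prior count.

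Most genes of cell division and of DNA replication fell. Of 36 mitosis genes, 34 fell and 0 rose, with 34 adjusted over the list alone, and the median log2 fold change was -0.94. The topoisomerase gene TOP2A fell by 1.42 from 547 ± 3.79 to 204 ± 8.92 CPM, the proliferation marker MKI67 fell by 1.39 from 344 ± 11.8 to 131 ± 10.1 CPM, the mitotic kinesin gene KIF23 fell by 1.19 and the mitotic regulator gene BIRC5 fell by 1.27. Of 38 DNA replication genes, 31 fell and 1 rose, and the counts were 31 and 1 adjusted over the list alone. The helicase subunit gene MCM6 fell from 86.6 ± 5.99 to 30.7 ± 4.25 CPM, the thymidine kinase gene TK1 fell by 1.22 and UHRF1 fell by 1.37. PCNA, the replication clamp and also a p53 target, was the gene that rose and was chosen after its values were seen; it rose by 0.89 from 189 ± 2.84 to 350 ± 24.8 CPM. Camera gave mitosis an adjusted p of 1.07e-14 and an adjusted p = 0.222 with an estimated correlation, and it gave DNA replication an adjusted p of 7.89e-09 and an adjusted p = 0.364 with an estimated correlation.

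Genes of the DNA damage and replication stress response went both ways, with 23 of 38 lower and 8 higher, and 23 and 8 adjusted over the list alone. PRKDC, the catalytic subunit of DNA-dependent protein kinase, fell by 1.54 from 879 ± 8.61 to 303 ± 11.1 CPM, the histone gene H2AX fell by 1.08 and the Ku subunit gene XRCC5 fell by 0.61, while NBN, of the MRE11 complex, rose by 0.70. In camera this list had an adjusted p of 0.00702, and an adjusted p = 0.276 with an estimated correlation. Of 41 factors that resolve or prevent R-loops, which are RNA-DNA hybrids with a displaced DNA strand, 17 fell and 7 rose, with 17 and 7 adjusted over the list alone. SSRP1, of the FACT histone chaperone, fell by 0.73 from 224 ± 10.6 to 135 ± 6.35 CPM, the helicase gene PIF1 fell by 1.46 and the helicase gene DHX9 fell by 0.52. The R-loop list did not pass camera, with a median log2 fold change of -0.11 and an adjusted p of 0.0613. Its adjusted p in camera was 0.049 without wild-type replicate 1, 0.0173 with no filter on low counts and 0.276 with an estimated correlation. Of 16 replication-dependent histone genes, 6 rose and 0 fell, and the counts were 6 and 0 adjusted over the list alone. H2AC6 rose to 82.2 ± 5.17 CPM, H2BC21 rose by 1.90, H2BC4 by 2.03 and H2BC5 by 0.77. The histone list did not pass camera, with an adjusted p of 0.108. This was 0.0284 with the filter of 1 CPM in 3 libraries and 0.467 with an estimated correlation. Histone genes are close paralogs whose reads can be shared, so these values are uncertain.

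Most messenger RNAs of the translation apparatus fell. Of 79 cytosolic ribosomal protein genes, 77 fell and 0 rose, with 77 adjusted over the list alone, and the median log2 fold change was -0.56. RPS2 fell by 1.38 from 1990 ± 30.1 to 766 ± 57.5 CPM, RPL4 fell by 1.15 from 2500 ± 54.4 to 1124 ± 17.4 CPM, RPL23 fell by 1.35 and RPS3A fell by 1.27. Of 45 translation factor genes, 28 fell and 5 rose, and the counts were 28 and 5 adjusted over the list alone. The elongation factor gene EEF2 fell by 1.36 from 2783 ± 72.9 to 1084 ± 28.7 CPM, EEF1A1 fell by 1.15 (SE 0.0339) from 9113 ± 275 to 4120 ± 69.2 CPM, the initiation factor gene EIF4B fell by 1.41, and the initiation factor gene EIF3L fell from 168 ± 3.01 to 59.3 ± 2.53 CPM. The 5 genes that rose, chosen after their values were seen, were EIF6 (0.50), EIF5 (0.46), EIF2S2 (0.29), EIF4A2 (0.17) and EIF4E (0.17). Camera gave ribosomal proteins an adjusted p of 7.46e-22 and an adjusted p = 0.276 with an estimated correlation, and it gave translation factors an adjusted p of 3e-05 and an adjusted p = 0.364 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes, and 25.6% of the exonic bases of RPS2 and 41.1% of those of EIF3L overlap another gene on the same strand, so their levels are uncertain. The mitochondrially encoded mRNAs, a list fixed as a sign of RNA quality, moved in the same direction, with a median log2 fold change of -0.55.

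The 13 mitochondrially encoded mRNAs all fell, with 13 adjusted over the list alone and a median log2 fold change of -0.55. MT-CO3, a subunit of cytochrome c oxidase, fell by 1.45 (SE 0.0382) from 5648 ± 185 to 2074 ± 104 CPM, MT-ATP8 and MT-ATP6, subunits of ATP synthase, fell by 1.35 and fell by 1.29, and MT-CYB, the cytochrome b gene, fell by 0.81. MT-ATP8 overlaps MT-ATP6 over 22.2% of its bases, so its count is uncertain. This list was fixed as a sign of RNA quality. The mitochondrial ribosomal RNAs, chosen after their values were seen, also fell: MT-RNR2 fell by 1.02 and MT-RNR1 fell by 0.73, and their share of counts was 1.68% in each wild-type library and between 0.839% and 0.87% in the knockout libraries. Camera gave an adjusted p of 1.98e-07, and an adjusted p = 0.276 with an estimated correlation.

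**Figure D3:**
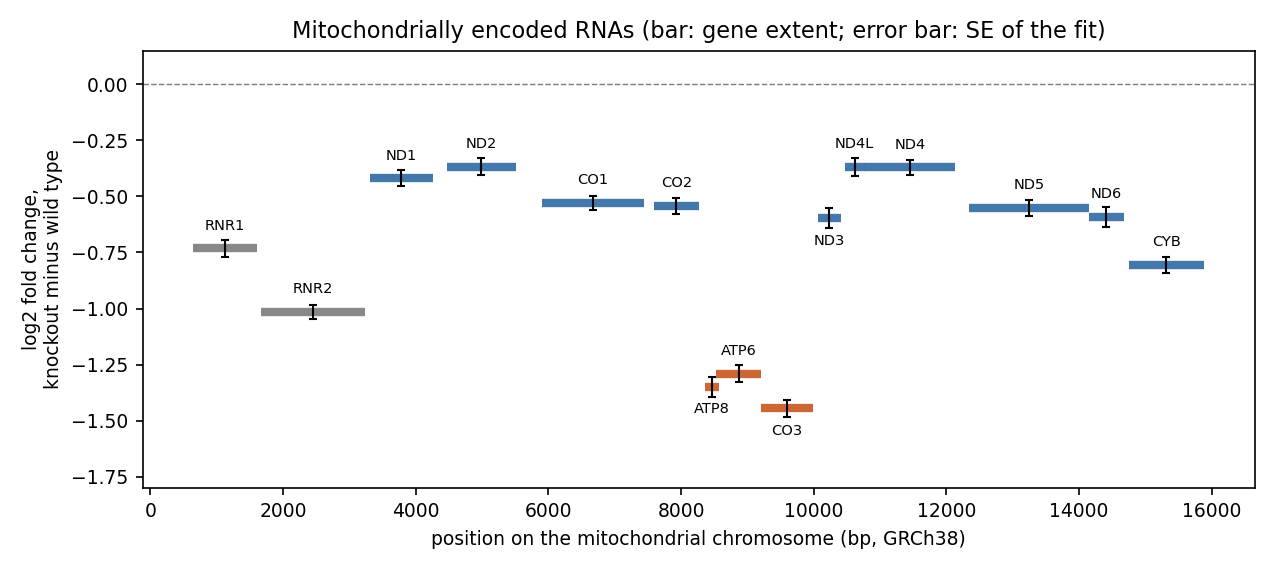
Log2 fold change (knockout minus wild type) of the mitochondrially encoded mRNAs and ribosomal RNAs by position on the mitochondrial chromosome in base pairs, with thick bars for gene extents and error bars for the SE of the fit. MT-ATP8, MT-ATP6 and MT-CO3, drawn in orange, lie between -1.45 and -1.29, below the other mRNAs at -0.81 to -0.37.

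The other writers, erasers and readers of m6A went both ways, with 10 of 28 genes higher and 11 lower, or 10 and 12 adjusted over the list alone. The reader gene FMR1 rose by 0.87 from 80.5 ± 4.96 to 147 ± 7.1 CPM and WTAP, of the methyltransferase complex, rose by 0.83 from 62.7 ± 3.23 to 112 ± 2.23 CPM. The reader genes IGF2BP3 and YTHDC2 fell by 0.68 and fell by 0.67. The list did not pass camera, with a median log2 fold change of -0.07 and an adjusted p of 0.651.

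Stress and metabolic gene lists held genes that moved in both directions. Of 32 NRF2 targets, 15 rose and 13 fell, with 15 and 13 adjusted over the list alone: the heme oxygenase gene HMOX1 rose by 1.42 and the cystine transporter gene SLC7A11 rose by 1.23, while AKR1B10 fell by 1.06. Of 34 genes of the unfolded protein and ATF4 responses, 16 rose and 14 fell, or 17 and 14 adjusted over the list alone: ATF3 rose by 3.05, STC2 by 1.35 and PPP1R15A by 1.06, while the chaperone gene PDIA4 fell by 1.15. Of 35 hypoxia and glycolysis genes, 18 rose and 9 fell by either adjustment, that is 18 and 9 adjusted over the list alone. The hexokinase gene HK2 rose by 3.12 from 6.27 ± 0.642 to 54.3 ± 3.29 CPM, the glucose transporter gene SLC2A3 by 1.52, the carbonic anhydrase gene CA12 by 1.22 and the lactate transporter gene SLC16A3 by 1.09. Of 25 cholesterol genes, 15 rose and 6 fell, with 15 and 6 adjusted over the list alone: STARD4 rose by 1.71 and INSIG1 by 0.93. Camera gave adjusted p-values of 0.944 for NRF2 targets, 0.796 for the unfolded protein and ATF4 responses, 0.0594 for hypoxia and glycolysis and 0.108 for cholesterol synthesis and uptake, so none of these 4 lists passed. The hypoxia list had adjusted p-values of 0.049 without wild-type replicate 1, 0.042 without knockout replicate 3 and 0.0126 with no filter on low counts. In camera with an estimated correlation its adjusted p was 0.586.

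Of 36 lysosomal genes, 19 rose and 8 fell, with 19 and 8 adjusted over the list alone: the cathepsin gene CTSS rose by 3.21 from 31.9 ± 4.93 to 298 ± 6.54 CPM, the cholesterol exporter gene NPC1 by 1.29, CTSL by 1.23 and LIPA by 1.01. Of 29 immediate-early genes, 16 rose and 6 fell, with 16 and 6 adjusted over the list alone: the phosphatase gene DUSP5 rose by 2.36 from 35.4 ± 4.79 to 180.5 ± 8.24 CPM, KLF6 by 1.36, JUN by 1.14 and FOSL2 by 0.78. Camera gave lysosomal genes an adjusted p of 0.0236 and an adjusted p = 0.53 with an estimated correlation, and it gave immediate-early genes an adjusted p of 0.0129 and an adjusted p = 0.364 with an estimated correlation.

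Genes of epithelial cells rose for 11 of 21 members and fell for 1, with 11 and 1 adjusted over the list alone. The adhesion gene CDH1 rose by 1.76 from 10.0 ± 1.69 to 34.0 ± 0.602 CPM, the tight junction gene CLDN1 by 1.08, the mucin gene MUC1 by 1.79 and the desmosome gene DSP by 0.70, and ST14, chosen after its values were seen, fell by 1.33. Of 24 targets of YAP and TEAD, 16 rose and 6 fell, with 16 and 6 adjusted over the list alone: IGFBP3 rose by 1.46, AMOTL2 by 1.48, NUAK2 by 1.18 and ASAP1 by 0.67. Camera gave epithelial genes an adjusted p of 0.00918 and an adjusted p = 0.161 with an estimated correlation, and it gave YAP and TEAD targets an adjusted p of 0.0116 and an adjusted p = 0.512 with an estimated correlation.

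Mesenchymal, matrix, Wnt and lung lineage genes did not pass camera as lists, although most members changed. Of 24 mesenchymal genes, 12 rose and 10 fell, with 12 and 10 adjusted over the list alone: the protease gene MMP2 fell by 2.19 and S100A4 fell by 1.20, while TWIST2 rose by 1.60. Of 39 extracellular matrix genes, 20 rose and 18 fell, or 20 and 19 adjusted over the list alone: VCAN fell by 1.27, LTBP4 fell by 1.09 and THBS1 fell by 1.27, and the list holds TNC. Of 19 Wnt targets, 11 rose and 3 fell, with 11 and 3 adjusted over the list alone: FZD7 rose by 2.22, DKK1 by 0.71 and NKD2 by 1.82, while ZNRF3 fell by 0.73. Of 14 alveolar type 2 and lung lineage genes, 3 rose and 5 fell, or 3 and 6 adjusted over the list alone. LAMP3, a lysosomal membrane protein that interferon also induces, rose by 7.46 from 0.363 ± 0.16 to 61.0 ± 3.21 CPM and GATA6 rose by 1.16, while ABCA3 fell by 0.60 and FOXA2 fell by 0.63. Camera gave adjusted p-values of 0.766, 0.944, 0.147 and 0.531 for these 4 lists in that order. The Wnt list had an adjusted p of 0.0208 with no filter on low counts and 0.512 with an estimated correlation. The mesenchymal list had a median log2 fold change of 0.21 and a mean of -0.04 with camera's direction up, the matrix list a median of 0.23 and a mean of -0.18 with the direction down, and the lung lineage list a median of -0.08 and a mean of 0.42 with the direction down.

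Markers of leukocytes and fibroblasts went both ways, and most endothelial markers did not pass the test. Of 21 leukocyte markers listed, 8 were tested, of which 4 fell and 1 rose, with 4 and 1 adjusted over the list alone: CD14 fell by 1.69 from 11.1 ± 0.243 to 3.45 ± 0.537 CPM, CORO1A fell by 2.25 and CSF1R fell by 2.71, while ITGAM rose by 0.54 from 3.24 ± 0.555 to 4.70 ± 0.424 CPM. CORO1A and CSF1R were low in both groups. CORO1A went from 0.848 ± 0.222 to 0.179 ± 0.0695 CPM and CSF1R from 0.803 ± 0.0541 to 0.114 ± 0.177 CPM. For ITGAM edgeR gave an adjusted p of 0.0112, and 0.0544 without wild-type replicate 3. Of 11 fibroblast markers tested, 6 fell and 3 rose, with 6 and 3 adjusted over the list alone. FBLN1 fell by 0.88 and COL6A3 fell by 3.64 from 2.83 ± 0.252 to 0.2345 ± 0.173 CPM, while TWIST2 rose as above and COL1A1 rose by 0.49. Of 5 endothelial markers tested, 1 rose and 0 fell, with 1 and 0 adjusted over the list alone, and EGFL7 rose by 0.36. Camera gave adjusted p-values of 0.17 for leukocyte, 0.286 for fibroblast and 0.531 for endothelial markers.

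Near YTHDF1 at 20q13.33, 8 of 19 genes rose and 3 fell, with 8 and 3 adjusted over the list alone. HELZ2, an interferon-induced helicase gene, rose by 4.88 from 25.6 ± 0.263 to 756 ± 10.8 CPM, OGFR by 1.91, NKAIN4 by 2.10 and ARFGAP1 by 0.62. The 3 genes that fell, chosen after their values were seen, were PPDPF (fell by 0.40), EEF1A2 (fell by 0.24) and DIDO1 (fell by 0.11). Camera gave an adjusted p of 0.0546, and 0.53 with an estimated correlation. It was 0.0312 without wild-type replicate 2, 0.0174 without knockout replicate 3, 0.0476 with library size only and 0.00706 with no filter on low counts. Of 15 nuclear long noncoding RNAs and small RNA hosts, 6 rose and 6 fell, with 6 and 6 adjusted over the list alone: SNHG16 rose by 0.70, while SNHG5 fell by 1.05, SNHG3 fell by 0.53 and KCNQ1OT1 fell by 0.77, and camera gave an adjusted p of 0.944. SNHG16 overlaps opposite-strand genes over 30.6% of its exonic bases, so its level is uncertain.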

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

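No alternative in this part was chosen after the results were seen. The count of 9893 changed genes was 9189 with DESeq2, 10021 with limma-voom, 9904 with RLE factors, 9892 with library size only, 9811 without a filter, 9366 with the filter of 1 CPM, 8211 at an adjusted p threshold of 0.01, and 9059 to 9486 with 1 library left out. It was 2294 with an absolute log2 fold change of at least 1 and 2585 with edgeR's test against a fold change of 1.5, because both ask for larger changes. No pairing of the samples by replicate number was seen, which does not exclude that they were prepared in pairs. Deviations from the group means of same-numbered libraries correlated at -0.026, -0.014 and 0.008, and not every sample correlated best with its own number. With the replicate block 9703 genes passed. YTHDF1 kept its call with each tool, scaling and filter, with the block and with each library left out, the settings run for it, with log2 fold changes from -1.07 to -1.02 with 1 library left out and -1.05 with the block. Another scaling moved the median log2 fold change of all genes by at most 0.027. Named genes kept their calls in 1869 of 1870 comparisons, the exception being ITGAM. Most were named for a large change or a small adjusted p in these same libraries. Their rate therefore says little about the other changed genes. The list count of 17 was 17 with the block, 17 to 19 with 1 library left out, 18 with library size only, 21 without a filter, 1 with an estimated correlation and 28 with fry. Fry does not compare a list with other genes. The estimated correlation was 0.003 for checkpoint genes, 0.004 for cytokines and -0.026 for epithelial genes, below the preset 0.01. These lists still lost their calls, so a correlation above the preset does not account for their loss. The other lists that lost a call had estimates from 0.036 for nucleic acid sensing to 0.538 for mitochondrial mRNAs. The cause of the lower count was not tested further. Of 460 comparisons of single lists, 422 kept their call, 16 lost it, all with the estimated correlation, and 21 gained one. The lung lineage list turned from down to up under fry, with an adjusted p of 0.000478, and the cause was not tested. Depth limits the size of change for the 41 changed genes with 0 wild-type counts and the 2 with 0 knockout counts, whose folds are bounds only.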

Other observations

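Every test in this part was chosen after the results it bears on were seen, except the comparison with lists matched on length and abundance and the overlap of MT-CO3 with other genes.

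Gene families grouped by the letters of their symbols gave groups that in part repeat members of the fixed lists, such as MCM6, PARP9, IRF7 and CCL5. Of 208 families with at least 10 tested genes, camera with Benjamini-Hochberg adjustment called 7, among them RPL, RPS and EEF, whose members the report describes in part. Of 10 CCL chemokine genes, 8 rose and 0 fell, with an adjusted p of 0.00178. Of 13 PARP genes, 10 rose and 1 fell, with an adjusted p of 0.00968. Of 12 genes whose symbols start with IRF, 8 rose and 0 fell, with an adjusted p of 0.0132. These 12 were grouped by letters alone and are not all interferon regulatory factors. All 11 MCM genes fell, with an adjusted p of 0.000482. None of these families passed with an estimated correlation, where the adjusted p = 0.598 with an estimated correlation for CCL, PARP and IRF and 0.658 for MCM. Among single genes chosen after their values were seen, RET, a receptor tyrosine kinase, rose by 7.13 from 0.204 ± 0.0578 to 29.8 ± 2.19 CPM, and SMTNL1 rose by 6.36 from 0.377 ± 0.282 to 33.9 ± 2.64 CPM. ACTN2, a muscle alpha-actinin, and TAC3, a tachykinin precursor, had 0 counts in the wild-type group and were at least 245-fold and 200-fold higher. Median log2 fold changes of single chromosomes over protein-coding genes lay between -0.1 and 0.052.

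The rise of the 47 interferon-stimulated genes was weighed against leukocyte RNA and against the making of the knockout line. Leukocytes in the knockout libraries would bring their abundant transcripts, and PTPRC, CD53, LAPTM5, TYROBP, CORO1A and LCP1 together reached 1.34 CPM there, against 29.8 CPM for CXCL10, which argues against them. What stays open is whether making or handling the knockout line, rather than loss of YTHDF1, raised these genes: 0 control lines that went through the same procedure are named in the labels, so these cannot be told apart. Loss of YTHDF1 remains a possible explanation that was not tested by any other perturbation here.

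The fall of ribosomal protein and elongation factor mRNAs was weighed next. In 10000 lists matched to the ribosomal protein genes on exonic length and mean CPM, the median log2 fold change was typically -0.046. The lowest was -0.297, against -0.56 observed. The small typical fall of matched genes argues against a bias by abundance or by exonic length. How close the 50 nearest genes came to each member was not measured. The lowest draw is no p-value, because genes of the list move together, with an estimated correlation of 0.465. Exonic length here counts every annotated exon of a gene, such as 5979 bases for RPL23, and can exceed the length of its mRNA. A bias tied to mRNA length was therefore not tested. The reads taken up by interferon-stimulated genes could give the other genes a log2 fold change of -0.032 at most. A candidate explanation is a shared fall of mRNAs with a terminal oligopyrimidine start. The 11 such translation factor mRNAs and the other 34 differed by -0.65 in mean log2 fold change (two-sided permutation test, p = 6e-05). Without the 5 of the 11 whose falls had prompted the idea, the difference was -0.33 (permutation p = 0.0548). Both permutations treat genes as independent replicates, which genes of the same libraries are not. Neither p-value therefore carries a conclusion, and these data leave the idea open.

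The fall of MT-ATP8, MT-ATP6 and MT-CO3, which are neighbours on the mitochondrial chromosome, was larger than that of the other 10 mitochondrial mRNAs. The difference in mean log2 fold change was -0.85 (SE 0.033 over libraries), which argues against an equal fall of every mitochondrial transcript; the ribosomal RNA MT-RNR2 fell by 1.02. Reads lost to gene overlap are argued against by MT-CO3, of which 0.13% of bases overlap another gene. For MT-ATP6, reads assigned to its nuclear copy are argued against by that copy, MTATP6P1 on chromosome 1, which had a log2 fold change of -1.33 rather than a rise. Reads dropped because they map to several places would not raise the copy. How such reads were treated is not given in the sources used here, so their loss was not tested. The uneven fall remains open, and no biological explanation was tested.

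Chance division of the 6 libraries cannot be excluded by counting, because 10 splits cannot give a share under 0.05. The real split gave 9893 genes and the other splits gave at most 0 in edgeR's quasi-likelihood test, with 150 to 212 genes at an unadjusted p under 0.05, and no other tool was run on them. As large a count came from 1 of the 10 splits for genes and 1 of the 10 for lists. The real split gave 17 lists in camera and the highest other split 15. Each of the other splits sets 2 libraries of a genotype and 1 of the other against the reverse, so part of the genotype difference stays between the groups and the rest adds to the spread within them. These splits are therefore no reference without a difference, for genes or for lists.

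The kit marks strand, and whether the counting used it is not given in the sources used here. Noncoding genes inside introns of an expressed coding gene had log2 fold changes that correlated across genes with those of the host at a Spearman rho of 0.308 for 171 pairs on the same strand and 0.301 for 166 pairs on opposite strands. Genes are not independent replicates, so no test is given. Some genes with much same-strand overlap had low counts, such as IRF9 with 0.314 CPM and 48.4% overlap and NUSAP1 with 0.55 CPM and 62.2% overlap, chosen after their values were seen, so their levels are uncertain.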
